A study of Mus musculus with 19 samples.

How the data were processed

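RNA from mouse hind-limb muscle was sequenced in 19 libraries, which the labels place in 4 groups: young lean (n = 4), young obese (n = 5), aged lean (n = 5) and aged obese (n = 5). Per the labels, the mice were male and of a strain spelled C657Bl/6J (read here as C57BL/6J), the young were 6 months old and the aged 20 to 21 months old. Lean mice ate a diet with 12% of its energy from fat and obese mice one with 60%. Per the labels' protocols, the tissue was gastrocnemius, reads were single-end, and RNA with an integrity number below 7 was left out. The series' design text instead names tibialis anterior, paired-end reads and an age of 21 to 24 months for the aged mice. The sample labels were followed here and the conflict stays open. Libraries are named by group and by a number in the order of the submitters' library numbers, which does not pair libraries across groups. No source used here says that each library came from its own animal, so p-values measure the spread between these samples.

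The deposited table holds, per the labels, 1 signal value per gene and library, normalized by the authors. STAR 2.78a, DESeq2, Partek and the mouse genome build mm39 are named in the submitters' processing notes, with no role or order. The annotation, the counting program and any filter are not given in the sources used here. The values behave as gene-level reads divided by 1 factor per library: the median ratio to the geometric mean library was the same in all 19 libraries, as median-of-ratios scaling leaves it. The value of 1 read, found from the steps between low values, lay between 0.903 and 1.09. With that step, 85.1 to 86.3% of values up to 200 reads were whole within 0.02 of a read, under the 95% set as the minimum, so whole reads were not recovered and no count test was run. The totals correspond to an estimated 15.1 to 17.8 M reads per library (median 16.3 M). The table lists 14707 genes, none of them a mitochondrially encoded gene, and the lowest gene reaches about 10 reads in its highest library. Of its symbols, 14323 are GENCODE M21 symbols and 14696 match these, RefSeq or a RefSeq synonym. The reference genome at hand is of another build than mm39, so no coordinates are given.

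Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend), after 1340 genes with a mean under 10 were left out and 13367 remained. Fold changes are on this scale, which understates the change of low genes. The 19 libraries entered 1 model with 4 group means and 1 spread per gene pooled over the groups. The model had 15 residual and 4.37 prior degrees of freedom. It gave 5 pairwise comparisons and the interaction (the diet effect in aged minus that in young mice). A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and all such p-values below come from limma. Of 37 gene and cell marker lists, 33 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and the self-contained test fry, stand beside it. The share of each adult myosin and the summed fibrillar collagens were compared with exact two-sided permutation tests, adjusted over 20 and 5 tests. The same test was used for the mean of the fatty acid list and for the clock and tendon scores, chosen after the data were seen and adjusted over 5 tests each. The smallest p these allow is 0.0159 for 4 against 5 libraries and 0.00794 for 5 against 5. Per-library scores and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

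The groups, tests, gene lists and other settings were fixed before the data were examined. So was the rule for naming genes. For each comparison it takes the 8 largest rises and the 8 largest falls among changed genes with a mean of at least 50 (predicted, Rik and pseudogene symbols left out). It adds up to 4 members with the lowest p of each list, and 12 genes in every comparison: Myh7, Myh2, Myh1, Myh4, Col1a1, Col3a1, Fbxo32, Trim63, Cdkn1a, Pdk4, Ucp3 and Adipoq. The text prints only part of the genes this rule takes, and 1 of the largest changes is not reported here. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, library weights, robust variance moderation, a residual component, the groups of a comparison alone and each library left out. A clock score, a tendon score and 2 pairs of left-out libraries were added after the data were seen. The clock score is the mean log2 value of Arntl, Npas2 and Clock minus that of Dbp, Per3, Tef, Hlf, Nr1d2 and Ciart. The tendon score is the mean log2 value of Tnmd, Scx, Mkx, Cilp2, Chad and Kera.

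The code was tested on simulated data with 13367 genes of which 100 changed at each fold. For the diet comparison in young mice it recovered 59 of 100 genes changed 1.5-fold and 80 of 100 changed 2-fold, with 7 false calls among 146. For that in aged mice it recovered 65 and 77, with 1 false call among 143. Genes were drawn independently, with 1 spread per gene in all groups, so these rates need not hold for the real libraries. All libraries held Y-linked transcripts (Ddx3y 1009 to 1585) and low Xist (0 to 27.8), as male tissue would.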

Results

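The data are gene-level values of 13367 expressed genes in 19 libraries of mouse gastrocnemius, the mixed-fibre calf muscle. Mice were young or aged and ate a lean or a high-fat diet, which made 4 young lean, 5 young obese, 5 aged lean and 5 aged obese libraries. Estimated depth was similar throughout, at 15.1 to 17.8 M reads. The series title asks how matrix remodelling and fibre type shift in muscle of mice that are both aged and obese, and the sections below give the effect of each factor alone and of both. The largest axis of variation held 21.2% of the variance and the next 15.8%. Young lean 1 correlated slightly less with its own group (mean r across genes 0.972) than with other groups (0.973), as did young obese 2 (0.973 and 0.976).

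In young mice, genes of fat use and of the extracellular matrix were higher on the high-fat diet. Pdk4, a kinase that turns glucose oxidation down, rose 4.86-fold (log2 2.28, SE 0.28, adjusted p = 0.000468; n = 5 and 4). Nmrk2, a nicotinamide riboside kinase, rose 7.17-fold (log2 2.84, SE 0.36). Col1a1, a chain of the main fibrillar collagen, rose 6.53-fold (log2 2.71, SE 0.55, adjusted p = 0.00673). Scn3b, a sodium channel subunit, fell by 1.48 on the log2 scale (SE 0.22), and the syntrophin Sntb1 fell by 1.49 (SE 0.31). In all, 1475 of 13367 genes changed, 762 upward and 713 downward, and 217 by more than 2-fold. The other large rises were Cilp2 (2.42), BC048679 (2.41), Angptl4 (2.38), Col1a2 (2.27) and Tnmd (2.18). The other large falls were Slc7a2 (-1.41), Ctxn3 (-1.40), Cep85l (-1.28), Arhgap26 (-1.27), Asb11 (-1.23) and Sh3rf2 (-1.17).

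Of 33 tested fatty acid uptake and oxidation genes, 18 rose, none fell and 15 did not pass (24 rose when adjusted over the list alone). They included the carnitine transferase Cpt1a (1.22) and the thioesterases Acot2 (1.56) and Acot1 (1.95), and the mitochondrial carrier Ucp3 rose by 1.42. Of 31 proteasome subunits, 19 fell and 12 did not pass (26 fell when adjusted over the list alone), with a median log2 change of -0.32. Psma6 (-0.36), Psmb7 (-0.32) and Psma3 (-0.35) were among them. Of 20 collagens, 14 rose and 6 did not pass (19 when adjusted over the list alone). The list's median change was 1.26, and the basement membrane chains Col4a1 (0.95) and Col4a2 (0.85) rose with Col5a3 (1.53). Col3a1 was at 1.79 with an adjusted p of 0.0552. Of 36 matrix glycoproteins and proteoglycans 18 rose and 1 fell (27 and 1 over the list alone), among them Sparc (1.33) and Ogn (0.69). Of 27 remodelling enzymes and inhibitors 8 rose (15 over the list alone), among them the lysyl oxidase Loxl2 (1.74) and the inhibitor Timp2 (0.69). Markers of other cells moved with these groups: 8 of 10 tendon genes (10 over the list alone, median 1.70) and 7 of 12 markers of fibro-adipogenic progenitors, the fibroblast-like cells of muscle (11 over the list alone), rose. Of 14 adipocyte markers 2 rose (3 over the list alone, median 0.51, camera adjusted p = 0.0483), and of 12 endothelial markers 2 rose (3 over the list alone, median 0.23, camera adjusted p = 0.0456). These 2 lists did not hold with an estimated correlation (adjusted p = 0.78 for each). By camera the 7 lists before them stood apart from other genes, with adjusted p between 7.23e-16 for the proteasome and 8.02e-07 for progenitors. None of the 7 held with an estimated correlation (adjusted p = 0.301 for each). By fry, adjusted p lay between 0.00502 and 0.0109.

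No slow fibre gene of 16 passed in young mice, and Myh7, the slow myosin, was at -0.35 (SE 0.33, adjusted p = 0.512). Of 17 fast fibre genes 3 rose and 1 fell, and the counts over the list alone were the same. Slc2a4, the insulin-regulated glucose transporter GLUT4, fell by 0.39 (SE 0.07), and Ugp2, which supplies glycogen synthesis, fell by 0.57 (SE 0.08). Among 19 clock genes 3 rose and 3 fell, adjusted over all genes and over the list alone. Per3 (-1.05) and Rora (-0.76) fell while Arntl (0.77) and Npas2 (1.34) rose. The summed fibrillar collagens Col1a1, Col1a2 and Col3a1 averaged log2 15.23 ± 1.09 (SD, n = 5) in young obese and 12.93 ± 1.32 (SD, n = 4) in young lean muscle, a difference that did not pass (exact permutation p = 0.0476, adjusted 0.0794).

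The count in young mice depended on single libraries, at 2695 without young lean 1, 673 without young lean 2, 786 without young lean 3, 868 without young lean 4, 955 without young obese 1, 843 without young obese 4 and 854 without young obese 5. It was 0 with the tendon score (the effects kept a median of 0.826 of their size while errors widened 1.52-fold), 137 with the clock score and 182 from the 2 young groups alone, 3421 with library weights, 521 without young lean 3 and young obese 3, whose embryonic myosin Myh3 stood at 925 and 1467, and 3396 without young lean 1 and young obese 2. Quantile normalization gave 640 rises and 903 falls in place of 762 and 713. Of the 16 genes with the largest changes, 15 kept their call in every run without 1 library, and Cep85l did not (adjusted p up to 0.107). Of the 73 list members with the lowest p 40 kept it and 33 lost it, Arntl (up to 0.0506) and Npas2 (up to 0.0886) among them.

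**Figure D1:**
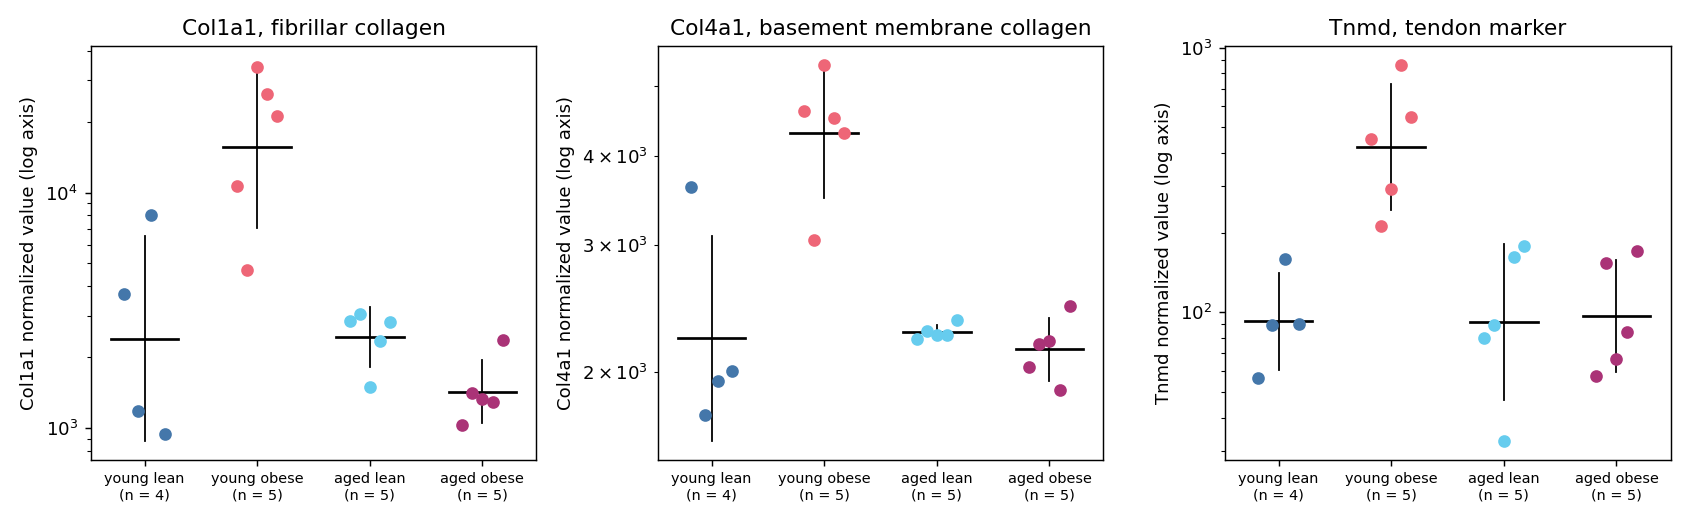
Normalized values of Col1a1 (fibrillar collagen), Col4a1 (basement membrane collagen) and Tnmd (tendon marker) per library on log axes, by group. Points are libraries, horizontal lines means and vertical lines 1 SD of log2 values. The groups do not overlap for Tnmd in young mice but do for Col1a1 and Col4a1, where young obese 2 (4707 and 3052) lies below the highest young lean library (7989 and 3619).

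In aged mice, genes of the slow contractile apparatus were higher on the high-fat diet, though carried slow muscle and a diet effect cannot be told apart. Tnni1, the slow troponin I, rose 3.88-fold (log2 1.96, SE 0.32, adjusted p = 0.011; n = 5 and 5), and Myh7 rose 3.48-fold (log2 1.80, SE 0.31, adjusted p = 0.0132). The slow troponins Tnnc1 (1.64) and Tnnt1 (1.47) rose with them. Car3, a carbonic anhydrase abundant in slow fibres, rose by 1.07 (SE 0.17), and the peptide transporter family member Slc15a5 fell by 1.47 (SE 0.20, adjusted p = 0.00323). In all 39 genes changed, 18 upward and 21 downward, while 1522 had an unadjusted p under 0.05. The 2 groups of each comparison alone gave 182 genes for diet in young and 143 for diet in aged mice. The main counts of 1475 and 39 therefore do not measure how far the diet effects differ in extent. Other rises were BC048679 (1.63), Rab15 (1.35) and Ces1d (1.19). Other falls were Prkcd (-1.04), Lrrc30 (-0.98), Dtnb (-0.94), Plekho1 (-0.87), Cd24a (-0.82), Cbr2 (-0.74) and Tmem37 (-0.70). Slc2a4 fell by 0.39 (SE 0.07), the same size as in young mice.

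Of 16 slow fibre genes 5 rose and 11 did not pass (14 rose when adjusted over the list alone), with a median of 0.93. The camera adjusted p was 2.12e-18 and the list did not hold with an estimated correlation (adjusted p = 0.309 with it; fry 0.0447). Of 17 fast fibre genes none passed, over all genes or the list alone, and Myh2, Myh1 and Myh4 were at 0.39, -0.12 and 0.10. No fatty acid gene of 33 passed over all genes and 7 rose over the list alone (median 0.31, camera adjusted p = 3.17e-12, adjusted p = 0.655 with an estimated correlation). The mean log2 value of the list averaged 10.92 ± 0.20 in aged obese and 10.55 ± 0.24 in aged lean muscle (SD, n = 5 each), without overlap (exact permutation p = 0.00794, adjusted 0.0397), and the same test did not pass in young mice (difference 0.76, exact permutation p = 0.0317, adjusted 0.0794). No adipocyte marker of 14 passed, over all genes or the list alone (median 0.26, camera adjusted p = 0.047, adjusted p = 0.835 with an estimated correlation). Endothelial markers (median 0.17) were also called by camera and did not hold with an estimated correlation (adjusted p = 0.80). No macrophage marker of 15 passed over all genes, and 11 fell over the list alone (median -0.91, camera adjusted p = 3.70e-10, adjusted p = 0.655 with an estimated correlation). Cd68 was at -1.42 and Adgre1 at -1.27. No collagen of 20 passed, over all genes or the list alone. The collagen (median -0.35) and matrix glycoprotein lists (median -0.16) were called by camera. Neither held with an estimated correlation (adjusted p = 0.835 for each) or by fry (adjusted p = 0.763 for each). The summed fibrillar collagens were lower in aged obese (log2 12.15 ± 0.38, SD, n = 5) than in aged lean muscle (13.08 ± 0.36, SD, n = 5), a difference of -0.92 (exact permutation p = 0.0159, adjusted 0.0397) that lost its call in 8 of 10 runs without 1 library. No marker of fibro-adipogenic progenitors of 12 passed over all genes, while 11 had a negative value and 2 fell over the list alone (median -0.29, camera adjusted p = 0.000213, adjusted p = 0.67 with an estimated correlation). With the mean of all 20 collagens in place of the sum the difference was -0.31 and did not pass.

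Myh7 made up 1.37 ± 0.743% of the 4 adult myosins in aged obese muscle and 0.411 ± 0.189% in aged lean muscle (SD, n = 5 each). The difference of 0.956 points did not pass over 20 tests (exact permutation p = 0.0159, adjusted 0.159). The smallest p that 5 against 5 libraries allow is 0.00794. A single share could therefore not pass over 20 tests even without overlap, and the missing call does not decide whether the share differed. The log2 ratio of Myh7 to Myh4 was 1.70 higher in aged obese than in aged lean muscle (3.25-fold). It did not pass over 5 tests (exact permutation p = 0.0159, adjusted 0.0595). In young muscle the share was 0.652 ± 0.219% on the lean diet (SD, n = 4) and 0.550 ± 0.268% on the high-fat diet (SD, n = 5). Myh4, the fastest myosin, held 88.6 to 90.0% of the sum on average in each group.

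**Figure D2:**
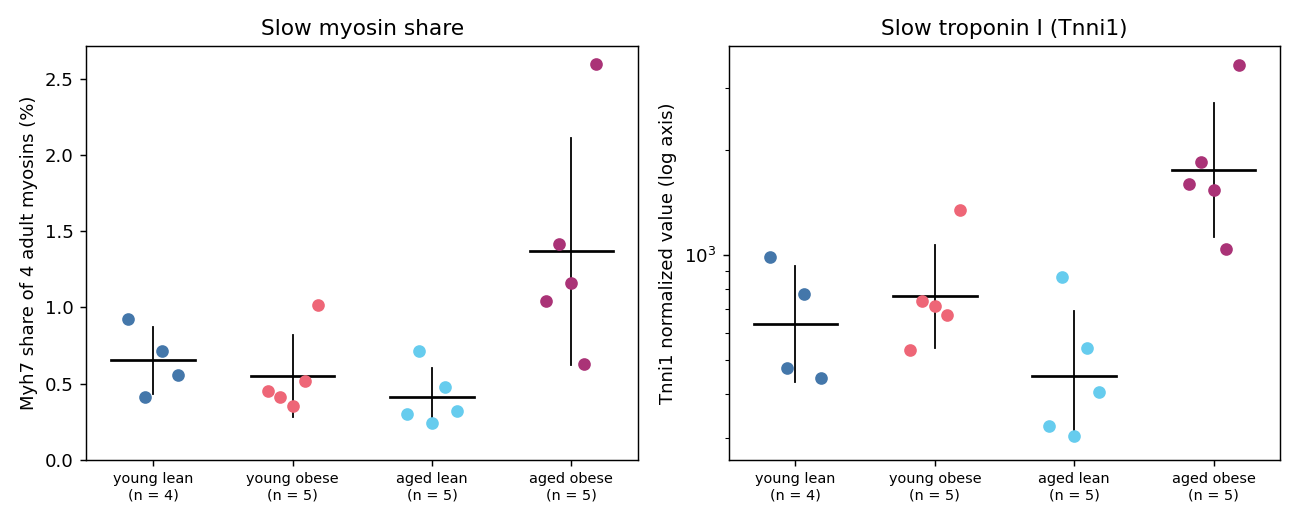
Share of Myh7 among 4 adult myosins (percent, left) and normalized value of Tnni1 (log axis, right) per library, by group. Points are libraries, horizontal lines means and vertical lines 1 SD, of log2 values on the right. The highest Myh7 share, 2.60%, is in aged obese muscle, where the mean is 1.37%.

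The count in aged mice was 70 without young lean 1, 60 without young obese 2, 66 without young obese 3, 23 without young lean 3, 23 without young obese 4, 11 without aged lean 1, 12 without aged lean 3, 23 without aged lean 5, 16 without aged obese 1, 6 without aged obese 2, 22 without aged obese 3 and 15 without aged obese 5, and 169 with library weights, 143 from the 2 aged groups alone, 320 with a residual component, 61 with the tendon score and 117 without young lean 1 and young obese 2. Of the 16 genes with the largest changes 3 (Car3, Slc15a5 and Lrrc30) kept their call in every run without 1 library. Myh7 lost it in 4 runs (without aged lean 1, aged lean 3, aged obese 2 or aged obese 5, adjusted p up to 0.0655), Tnni1 in 1 (without aged obese 2) and Slc2a4 in 2 (adjusted p up to 0.0623). None of the 6 list members with the lowest p kept it in every run.

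On the lean diet, Krt18, Tmem132b and Syt9 had the largest rises with age. Krt18, a keratin of simple epithelia, rose 14.2-fold (log2 3.83, SE 0.71, adjusted p = 0.00564; n = 5 and 4), from 8.61 ± 3.98 to 172 ± 148 (SD). Tmem132b rose 6.96-fold (log2 2.80, SE 0.17, adjusted p = 1.18e-08), and Syt9, a synaptotagmin, rose 6.16-fold (log2 2.62, SE 0.30). Hr, a corepressor of nuclear receptors, fell by 1.16 (SE 0.10, adjusted p = 4.68e-06). In all 545 genes changed, 279 upward and 266 downward, and 98 by more than 2-fold. Other large rises were Ccl8 (2.20), Fam174b (2.00), Kcnab1 (1.99), Dupd1 (1.92) and Cpne2 (1.89). Other large falls were Slc4a8 (-1.28), Slc7a2 (-1.12), Arhgap26 (-1.07), Lingo3 (-1.05), Banp (-1.03), Mlf1 (-0.98) and Fibin (-0.97).

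Of 28 interferon-stimulated genes 1 rose (6 over the list alone), H2-K1 of antigen presentation by 0.82, with a list median of 0.60 (camera adjusted p = 6.76e-07, adjusted p = 0.727 with an estimated correlation). Of 24 cytokine and chemokine genes 3 rose (6 over the list alone): Cxcl10 (2.19), Ccl8 and Tnfrsf12a (1.28). No macrophage marker of 15 passed over all genes and 5 rose over the list alone (median 1.04, camera adjusted p = 4.95e-05, adjusted p = 0.727 with an estimated correlation). No marker of fibro-adipogenic progenitors of 12 passed over all genes and 6 rose over the list alone (median 0.45, camera adjusted p = 0.000151, adjusted p = 0.727 with an estimated correlation). No neutrophil marker of 7 passed over all genes and 4 fell over the list alone (median -2.61, camera adjusted p = 0.00186, adjusted p = 0.727 with an estimated correlation). Of 24 glycolysis and glycogen genes 3 fell (4 over the list alone), Pgk1 by 0.50, Ugp2 by 0.36 and Gys1 by 0.31. Of 31 proteasome subunits 1 fell (3 over the list alone, median -0.14, camera adjusted p = 4.05e-06, adjusted p = 0.727 with an estimated correlation). Of 20 junction and denervation genes 1 fell (1 rose and 1 fell over the list alone), with 15 positive values and a median of 0.48 (camera adjusted p = 0.03, adjusted p = 0.727 with an estimated correlation). The cytokine and glycolysis lists did not hold with an estimated correlation either (adjusted p = 0.727 for each), and the fry adjusted p of these 8 lists lay between 0.214 and 0.226. Arntl rose by 0.85. Of 20 collagens and 16 slow fibre genes none passed, over all genes or the lists alone, and Col1a1 was at 0.02.

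The count on the lean diet was 1271 without young lean 1, 337 without young lean 2, 283 without young lean 3, 324 without aged lean 1, 318 without aged lean 2 and 349 without aged lean 5, and 1565 with library weights, 1215 with a residual component, 206 with the clock score, 130 from the 2 lean groups alone, 355 without young lean 3 and young obese 3, and 1489 without young lean 1 and young obese 2. Of the 16 genes with the largest changes 13 kept their call in every run without 1 library, and Ccl8 (adjusted p up to 0.137), Arhgap26 (up to 0.0783) and Fibin (up to 0.0799) did not, nor did Cxcl10 (up to 0.0896), Tnfrsf12a (up to 0.117) and H2-K1 (up to 0.0784). Of 27 list members with the lowest p 11 kept it.

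On the high-fat diet, aged muscle had far less matrix transcript than young muscle. Its tendon score was lower too (6.23 against 8.36 on average, without overlap). Carried tendon in the young obese samples and an effect of age therefore cannot be told apart. Col1a1 fell by 3.45 on the log2 scale (SE 0.52, adjusted p = 0.000774; n = 5 and 5), and Col1a2 (-2.96, SE 0.40) and Col3a1 (-2.65, SE 0.55) fell with it. Cilp2, a cartilage and tendon matrix protein, fell by 3.43 (SE 0.46), and Kera, a keratan sulfate proteoglycan, fell by 3.31 (SE 0.44). Krt18 rose 18.2-fold (log2 4.19, SE 0.67), and Sln, which lowers the calcium uptake of the sarcoplasmic reticulum, rose 7.13-fold (log2 2.83, SE 0.64, adjusted p = 0.00974). In all 1206 genes changed, 556 upward and 650 downward, and 254 by more than 2-fold. Other large falls were Col11a1 (-3.31), C1qtnf3 (-3.20), Adam12 (-2.88) and Sfrp2 (-2.74). Other large rises were Mss51 (1.97), Kcnab1 (1.94), Rhpn2 (1.87), Ppp1r14bl (1.78), Tekt1 (1.66) and Cpne2 (1.61).

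Of 20 collagens 16 fell and 4 did not pass (18 over the list alone, median -1.57). With the tendon score in the model none passed, and their median was -1.03. Of 36 matrix glycoproteins 23 fell and 1 rose (30 and 2 over the list alone), with Sparc at -1.66 and Thbs4 at -1.76. Of 27 remodelling genes 16 fell (18 over the list alone), such as Adamts2 (-1.30) and the gelatinase Mmp2 (-1.26). Tendon markers moved with them, 8 of 10 falling (9 over the list alone, median -2.10), as did markers of fibro-adipogenic progenitors, with 4 of 12 falling (7 over the list alone, median -0.51, camera adjusted p = 9.44e-06, fry 0.0237, adjusted p = 0.371 with an estimated correlation). Camera gave adjusted p of 1.17e-18 for collagens, 1.62e-15 for glycoproteins, 7.35e-12 for remodelling genes and 4.50e-10 for tendon markers. None of these 4 held with an estimated correlation (adjusted p = 0.235 for each). The fry adjusted p was 0.00118 for collagens and 0.00134 for tendon markers. Endothelial (median -0.18) and smooth muscle and pericyte markers (median -0.23) were also called by camera. Neither held with an estimated correlation (adjusted p = 0.667 for each). The summed fibrillar collagens differed by -3.07 on the log2 scale (exact permutation p = 0.00794, adjusted 0.0397), and the groups did not overlap, though the call was lost in 4 of 10 runs without 1 library. Over the 10 runs the difference lay between -3.48 and -2.77, and 4 against 5 libraries allow no exact permutation p under 0.0159.

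Of 16 slow fibre genes 4 rose (10 over the list alone, median 0.65), Myh7 2.59-fold (log2 1.37, SE 0.31) and Tnni1 by 1.20 (SE 0.32). Of 20 neuromuscular junction and denervation genes 5 rose and 15 did not pass (9 over the list alone), such as the acetylcholine receptor subunit Chrnb1 (0.89), Gadd45a (1.28) and Sln. Of 29 calcium handling genes 4 rose (7 over the list alone), such as Camk2b (0.85) and Cacng1 (0.92). Of 31 proteasome subunits 5 rose (20 over the list alone, median 0.22). The slow fibre and proteasome lists did not hold with an estimated correlation (adjusted p = 0.371 for each). Nor did the junction list (adjusted p = 0.235 with an estimated correlation) or the calcium list (adjusted p = 0.667 with an estimated correlation). By fry, adjusted p was 0.0386 for slow fibre, 0.0262 for proteasome, 0.0130 for junction and 0.108 for calcium genes. Pdk4 fell by 0.95, Ucp3 by 1.26 and Cpt1a by 0.62, and 3 of 33 fatty acid genes fell (3 over the list alone). Bbc3, a pro-death target of p53, rose by 1.19 and the receptor Eda2r by 1.53, 2 of 20 p53 and senescence genes (2 over the list alone).

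The count on the high-fat diet was 1893 without young obese 2, 774 without young obese 4, 787 without young obese 5, 723 without aged obese 2 and 756 without aged obese 3, and 2840 with library weights, 1841 with a residual component, 306 with the clock score, 12 with the tendon score, 786 without young lean 3 and young obese 3, and 2523 without young lean 1 and young obese 2. Of the 16 genes with the largest changes 14 kept their call in every run without 1 library, and C1qtnf3 (adjusted p up to 0.0708) and Adam12 (up to 0.0652) did not, nor did Tnni1 (up to 0.0681), Pdk4 (up to 0.0797), Gadd45a (up to 0.099) and Eda2r (up to 0.0552). Of 66 list members with the lowest p 36 kept it. Quantile normalization gave 769 rises and 623 falls in place of 556 and 650.

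**Figure D3:**
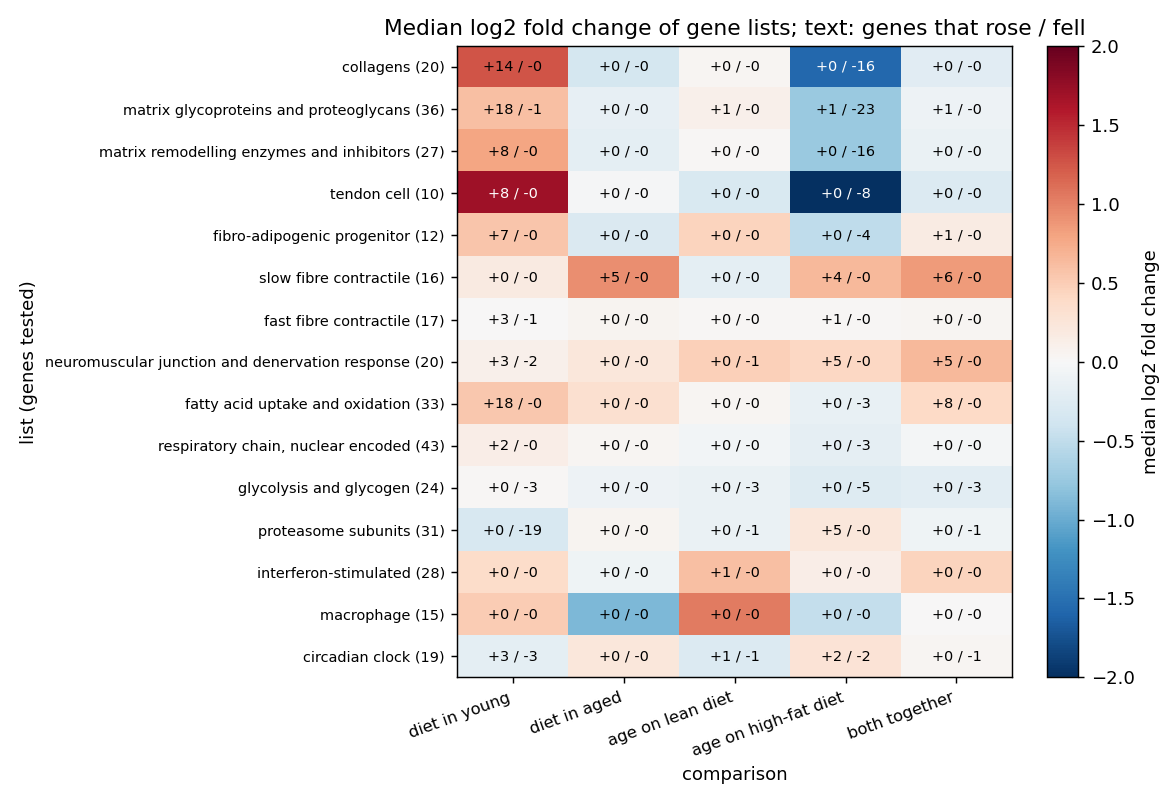
Median log2 fold change of 15 gene lists (vertical axis, with genes tested) in 5 comparisons (horizontal axis), as colour. The text in each field gives members that rose and fell. Collagens have 14 rises with diet in young mice and 16 falls with age on the high-fat diet.

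Aged obese muscle was also compared with young lean muscle. Krt18 rose 14.9-fold (log2 3.90, SE 0.71, adjusted p = 0.00303; n = 5 and 4), and Mss51, a protein of muscle metabolism, rose 6.72-fold (log2 2.75, SE 0.45). Lep, the adipocyte hormone leptin, rose 6.61-fold (log2 2.72, SE 0.65). S100a9, a neutrophil protein, fell by 3.46 (SE 0.88, adjusted p = 0.0272), and Fkbp5, a glucocorticoid-induced chaperone, fell by 1.50 (SE 0.30). The neutrophil list (median -2.16) was called by camera and did not hold with an estimated correlation (adjusted p = 0.827). In all 746 genes changed, 434 upward and 312 downward, and 165 by more than 2-fold. Other large rises were Tmem45b (2.36), Tmem132b (2.31), Igfn1 (2.25), Rab15 (2.16) and Nnat (2.12). Other large falls were Banp (-1.56), Slc25a25 (-1.54), Sntb1 (-1.37), Osgin1 (-1.28) and Mlf1 (-1.23).

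Of 16 slow fibre genes 6 rose (14 over the list alone, median 0.86), among them Tnni1 (1.46), Myl6b (0.82) and Myom3 (1.11), while Myh7 was at 1.02 with an adjusted p of 0.0738. Of 33 fatty acid genes 8 rose (15 over the list alone, median 0.40), with Acot2 (1.34) and Pdk4 (1.33) the lowest in p. Of 20 junction and denervation genes 5 rose (9 over the list alone), among them Colq (0.77), which anchors acetylcholinesterase. Of 24 glycolysis and glycogen genes 3 fell (5 over the list alone), with Pgk1 at -0.69. By camera the slow fibre and fatty acid lists had an adjusted p of 3.66e-09, the junction list 4.43e-05 and the glycolysis list 3.05e-05. The slow fibre, junction and glycolysis lists did not hold with an estimated correlation (adjusted p = 0.599 for each). Nor did the fatty acid list (adjusted p = 0.827 with an estimated correlation). By fry, adjusted p was 0.0188 for the junction and glycolysis lists, 0.0515 for slow fibre and 0.180 for fatty acid genes. Slc2a4 fell by 0.55 (SE 0.07, adjusted p = 0.000173). Of 24 cytokine and chemokine genes 4 rose, with Ccl5 at 2.77 and Cxcl9 at 2.09 (6 rose and 1 fell over the list alone). None of 20 collagens passed, over all genes or the list alone.

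The count of aged obese against young lean was 491 without young lean 2, 451 without young lean 3, 436 without aged obese 2 and 440 without aged obese 3, and 1711 with library weights, 389 from the 2 groups alone, 493 without young lean 3 and young obese 3, and 1219 without young lean 1 and young obese 2. Of the 16 genes with the largest changes 10 kept their call in every run without 1 library, and Lep (adjusted p up to 0.0701), Tmem45b (up to 0.0659), Igfn1 (up to 0.0726), Nnat (up to 0.128), S100a9 (up to 0.083) and Slc25a25 (up to 0.107) did not, nor did Tnni1, Myom3, Ccl5 and Cxcl9. Of 44 list members with the lowest p 22 kept it.

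Whether the diet acted differently in aged and young mice was tested as the interaction. Myh7 had the most positive value among the named genes (log2 2.15, SE 0.45, adjusted p = 0.02), since it was at -0.35 with the diet in young and at 1.80 in aged mice. Col1a1 (-3.48, SE 0.76), Col1a2 (-3.08), Nmrk2 (-2.62) and Pdk4 (-1.71) had negative values. In all 398 genes had a different diet effect, 172 with a positive and 226 with a negative difference. Of these, 314 changed with the diet in young mice and 16 in aged mice, and 363 had diet effects of opposite sign. A large difference favours opposite signs, and most of these genes did not pass in aged mice. The signs therefore do not show a reversed effect. Other positive values were those of Adamts20 (1.52), Per3 (1.50), Slc7a2 (1.41), Sh3rf2 (1.41), Rhpn2 (1.33), Scn3b (1.28) and Fzd4 (1.18). Other negative values were those of Kera (-2.91), Cilp2 (-2.68), Sfrp2 (-2.64), Cacna2d4 (-2.43) and the macrophage marker Adgre1 (-2.38).

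Of 20 collagens 10 had a lower diet effect in aged mice (15 over the list alone, median -1.74), such as Col5a3 (-1.92) and Col6a1 (-1.82). Tendon markers (median -1.53, 2 of 10 lower, 10 over the list alone) and markers of fibro-adipogenic progenitors (median -0.84, 4 of 12 lower, 11 over the list alone) moved with them, with camera adjusted p of 2.16e-06 and 2.17e-09 (adjusted p = 0.365 with an estimated correlation for each). Of 31 proteasome subunits 5 had a higher one (25 over the list alone, median 0.37). Of 16 slow fibre genes it was 1, Myh7 (5 over the list alone, median 0.79). Camera gave adjusted p of 3.42e-13 for collagens, 3.84e-15 for the proteasome and 2.37e-05 for slow fibre genes. None held with an estimated correlation (adjusted p = 0.365 for collagens and proteasome and adjusted p = 0.588 for slow fibre genes). By fry, adjusted p was 0.019 for collagens and progenitors, 0.0207 for the proteasome, 0.0319 for tendon markers and 0.164 for slow fibre genes. With the tendon score in the model no collagen passed (median -1.02). Carried tendon and a different diet effect on collagens therefore cannot be told apart.

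Diet effects in young and aged mice shared 4 genes higher in both (1.03 expected of independent lists) and 3 lower in both (1.12 expected), and 4 went opposite ways. Only 39 genes were called with diet in aged mice, which limits these counts. Across genes, which are not independent replicates, r was -0.043. Age effects on the lean and high-fat diet shared 69 higher genes (11.6 expected) and 45 lower genes (12.9 expected), with 12 opposite and r = 0.15 across genes. These pairs of comparisons have no library in common but share 1 pooled spread per gene. The expected counts leave that out, and a gene with a small spread is called more readily in both.

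The interaction count was 1724 without young lean 1 and 1312 without young obese 2, and lay between 112 and 224 in 14 other runs: 112 without young lean 2, 219 without young lean 3, 224 without young lean 4, 206 without young obese 1, 179 without young obese 3, 189 without young obese 4, 178 without young obese 5, 195 without aged lean 1, 192 without aged lean 2, 119 without aged lean 5, 192 without aged obese 1, 198 without aged obese 2, 186 without aged obese 3 and 181 without aged obese 4. It was 2494 with library weights, 1376 with a residual component, 134 without young lean 3 and young obese 3, 2694 without young lean 1 and young obese 2, 5 with the clock score and 0 with the tendon score. Of the 16 named genes with the largest values 7 kept their call in every run without 1 library. The others were Adamts20, Slc7a2, Rhpn2, Scn3b, Col1a1 (adjusted p up to 0.0551), Kera, Cilp2, Sfrp2 and Adgre1, and Pdk4 also lost its call. Of 37 list members with the lowest p 14 kept it.

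Myh2, Myh1, Myh4, the ligases Fbxo32 and Trim63, the cell cycle inhibitor Cdkn1a and the adipokine Adipoq, named in advance, passed in none of these comparisons. Cdkn1a was at 1.24 with age on the lean diet (adjusted p = 0.0998) and at 1.26 with both together (adjusted p = 0.0854).

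The clock score, higher where Arntl, Npas2 and Clock are high, averaged -2.58 ± 0.85 in young lean (SD, n = 4), -1.46 ± 0.64 in young obese, -1.52 ± 0.59 in aged lean and -2.48 ± 0.47 in aged obese libraries (SD, n = 5 each). None of its 5 pairwise differences passed (exact permutation tests, adjusted p 0.0595 to 0.81).

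**Figure D4:**
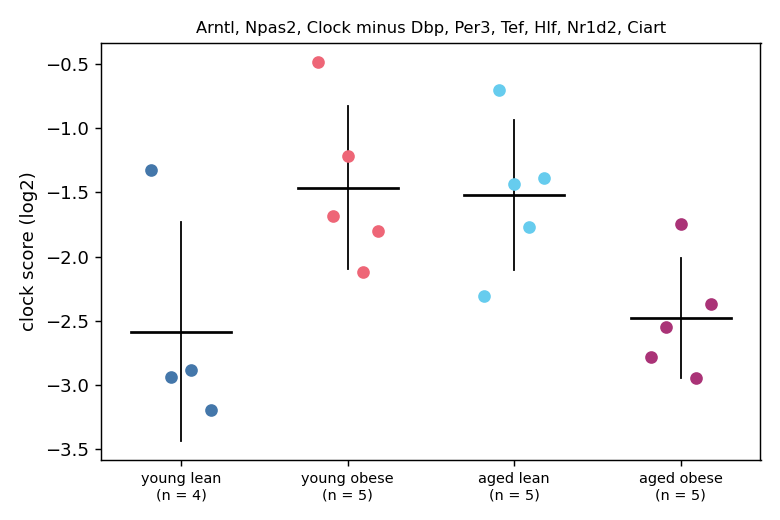
Clock score per library (log2, mean of Arntl, Npas2 and Clock minus mean of Dbp, Per3, Tef, Hlf, Nr1d2 and Ciart), by group. Points are libraries, horizontal lines means and vertical lines 1 SD. The group means lie between -2.58 and -1.46.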

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

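The tests of Myh2 and of clock phase within groups, and both tests of the labels of young lean 1 and young obese 2, were chosen after the result was seen. The rule that a value must go past its bound by more than its error was added to the tendon test after its result.

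Of 72 groups of libraries, 7 held a library far from the others of its group, and chance marks about 1 in 20 groups. Aged obese 5 stood apart in Myh2 share (8.94%), Myh4 share (83.0%) and Col1a1 (2363). Young obese 5 stood apart in Myh7 share (1.02%) and young lean 1 in clock score (-1.32). Trim63, a ubiquitin ligase of atrophy, stood apart in young obese 3 (5032) and aged lean 3 (3919).

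A different diet effect in aged and young mice, by the interaction test in limma, marked 398 genes. The named ones with positive values were Myh7 (2.15), Adamts20 (1.52), Per3 (1.50), Slc7a2 (1.41), Sh3rf2 (1.41), Rhpn2 (1.33), Scn3b (1.28) and Fzd4 (1.18). Those with negative values were Col1a1 (-3.48), Col1a2 (-3.08), Kera (-2.91), Cilp2 (-2.68), Sfrp2 (-2.64), Nmrk2 (-2.62), Cacna2d4 (-2.43), Adgre1 (-2.38) and Pdk4 (-1.71). The same test marked 17 lists by camera at the preset correlation, none of them with an estimated correlation. Their median log2 interactions were positive for slow fibre genes (0.79), clock genes (0.51), proteasome subunits (0.37), atrophy-linked ligases (0.20) and calcium handling (0.14). They were negative for collagens (-1.74), tendon markers (-1.53), macrophage markers (-1.36), matrix remodelling genes (-0.94), matrix glycoproteins (-0.91), fibro-adipogenic progenitors (-0.84) and Schwann cell and nerve markers (-0.53). The same held for cytokines (-0.50), interferon-stimulated genes (-0.49), lipid synthesis (-0.35), fatty acid use (-0.24) and the nuclear-encoded respiratory chain (-0.11).

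Collagens and tendon markers rose together in young obese muscle, which could come from tendon or fascia taken with the muscle. With the tendon score in the model the median over 7 basement membrane genes, which tendon holds little of, was 0.70 (SE 0.226) against 0.69 (SE 0.147) without it. Their calls ended because the score separates the young groups and widened the errors 1.52-fold. Since the groups do not overlap in the score, the fit extrapolates from the spread within groups. The test therefore does not decide whether tendon or fascia is their source. For the 14 called collagens the median went from 1.38 (SE 0.302) to 0.94 (SE 0.453). That is above the bound set beforehand, 0.5 of the first value, by less than its error, so for them tendon and a diet effect cannot be told apart. Regeneration in young lean 3 and young obese 3 does not account for it, since 12 of 14 collagens stayed called without both.

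Slow fibre genes rose in aged obese muscle, and a piece of slow muscle such as soleus might have been taken with some samples. Soleus also holds much Myh2, which was at 0.39 (95% interval -0.24 to 1.02), too wide to decide, so carried soleus and a shift of fibres within the muscle cannot be told apart. The effect did not come from 1 aged obese library, as the lowest median with 1 left out was 0.74 against 0.93 with all. Aged obese 5, left out in that run, held the highest shares of both Myh7 (2.60%) and Myh2 (8.94%).

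Some clock genes changed between groups, though no pairwise difference of the clock score passed. Libraries taken at different times of day would also show such changes. Within groups the 2 arms of the clock score went opposite ways (r = -0.69, permutation p = 0.0019), the relation that phase needs. Collection times are not in the labels, so phase and an effect of diet or age on the clock stay open. Whether phase is the whole cause of the diet effect in young mice cannot be decided with the clock score as a covariate. It is a single contrast of a few clock genes and need not take up phase in full. With it in the model the effects kept a median of 0.848 of their size. Their median went from 0.48 (SE 0.122) to 0.40 (SE 0.140), and 137 genes were called in place of 1475, since the score takes up part of the effect and widens the errors.

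Young lean 1 and young obese 2 resembled other groups slightly more than their own. Exchanged labels are argued against by the fatty acid score, which put young obese 2 at 0.90 of the way from the other young lean to the other young obese libraries. A wrong label of young lean 1 alone could not be excluded. At 7 of 26 risen fatty acid genes it lay below all young obese libraries, where an even chance among obese libraries gives 4.33. Its fatty acid score stood at 0.67 of the way to the young obese libraries. Over all 2695 genes changed without it, it lay beyond all young obese libraries at 888, where an even chance gives 449. Both chance counts are likely too low, since the genes were chosen for the distance of these same young obese libraries from the other young lean ones. The genes are also correlated, so neither count decides the label. Against a wrong label, its Pdk4 was 4149 (young obese 14706 to 29723) and its tendon score 5.99 (young obese 7.67 to 9.13), but these are single measures.

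Other splits of the same libraries gave as many genes in 3 of 100 cases for diet in young mice, the real one included. For the 5 other counts it was 1 of 100, the real one. These shares are not adjusted over the 6 counts. For diet in young mice other splits reached the real count, so chance is not excluded there. For the interaction the diet labels were shuffled within each age, so its splits speak to any diet effect rather than to a different one. The highest other counts were 2625 for diet in young mice (1475 real), 8 for diet in aged (39 real), 309 for age on the lean diet (545 real), 988 for age on the high-fat diet (1206 real), 158 for both together (746 real) and 324 for the interaction (398 real). The split with 2625 exchanged young lean 1 and young obese 2 and points to structure among these samples.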

How the results depend on the processing

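The clock score, the tendon score and the 2 pairs of left-out libraries were chosen after the results were seen. Counts are given in the order diet in young, diet in aged, age on lean, age on high-fat, both together and interaction. They were 3421, 169, 1565, 2840, 1711 and 2494 with library weights. A residual component gave 320 for diet in aged, 1215, 1841 and 1376 for age on lean, age on high-fat and interaction. The clock score gave 137, 206, 306 and 5 for diet in young, age on lean, age on high-fat and interaction. The tendon score gave 0 for diet in young, 61 for diet in aged, 12 for age on high-fat and 0 for the interaction. The groups of a comparison alone gave 182, 143, 130 and 389 for diet in young, diet in aged, age on lean and both together. Without young lean 3 and young obese 3 they were 521, 355, 786, 493 and 134, with diet in aged within 1.5 times. Without young lean 1 and young obese 2 they were 3396, 117, 1489, 2523, 1219 and 2694. Other counts stayed within 1.5 times.

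Without 1 library each, counts were 673 to 2695, 6 to 70, 283 to 1271, 723 to 1893, 436 to 1078 and 112 to 1724. The summed collagens were 1.91 to 2.80 for diet in young (1 run newly passed), -1.08 to -0.82 for diet in aged (8 of 10 runs lost the call) and -3.48 to -2.77 for age on high-fat (4 of 10 lost it, at 4 libraries against 5). The mean of the collagen list gave -0.31 for diet in aged (adjusted p = 0.146). At an adjusted p under 0.1 the diet effects shared 11 higher and 7 lower genes, and the age effects 149 and 89.

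With the clock score 7 medians of called lists changed sign. In the interaction fatty acid use (0.26) and the nuclear-encoded respiratory chain (0.13) passed the other way, and atrophy-linked ligases (-0.099), clock genes (-0.098) and Schwann cell and nerve markers (0.039) did not pass. The others, neither passing, were atrophy-linked ligases for diet in aged (-0.015) and fatty acid use for age on high-fat (0.111). With the tendon score 5 medians changed sign and did not pass: tendon markers for diet in young (-0.0023), age on high-fat (0.25) and interaction (0.21), and fatty acid use (0.048) and smooth muscle markers (0.046) for age on high-fat. Tendon markers are part of that score. Among called named genes Fmod changed sign with it for diet in young (-0.076). Of 71 list calls, 0 held with an estimated correlation, 26 with fry, 49 with the clock score and 52 with the tendon score. Of 327 called named genes 182 lost the call with the clock score, 213 with the tendon score, 99 without young lean 3 and young obese 3, 29 with robust moderation, 24 with quantile normalization, and 154 in at least 1 run without 1 library. With the groups of a comparison alone 103 of 280 lost it. The groups alone also replace a spread that the main model pools over 4 groups, and the groups differ in it. The log2 fibrillar collagen sum had an SD of 1.32 in young lean and 1.09 in young obese libraries. In aged lean libraries it was 0.36 and in aged obese 0.38. Apart from this spread and the smaller or larger number of libraries, the cause was not tested. Rescaling by the median ratio moved almost nothing, since the table is already on that scale. DESeq2 and edgeR on recovered reads were not run, as whole reads were not recovered. Robust moderation gives no camera value, and the groups alone give no interaction. At an estimated 15.1 to 17.8 M reads, genes under a mean of 10 were not tested, and the self-test recovered 59 of 100 genes changed 1.5-fold. Smaller changes, correlated genes and groups of unequal spread were not simulated.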

Other observations

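Myh3, the embryonic myosin of regenerating fibres, averaged 306 ± 58.9 in aged obese and 99.5 ± 30.6 in aged lean muscle (SD, n = 5 each), with ranges of 207 to 349 and 60.6 to 134. The gene was at 1.64 with diet in aged mice and did not pass (SE 0.77, adjusted p = 0.426 by limma). In young muscle 2 libraries stood high, young lean 3 (925) and young obese 3 (1467). The SE of 0.77 is pooled over all 4 groups, these 2 libraries included. It therefore does not measure the spread within the aged groups, whose ranges do not overlap.

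Saa3, an acute-phase protein, averaged 56.7 ± 63.5 in aged lean and 1.58 ± 1.33 in aged obese muscle (SD, n = 5 each). It was at -3.50 with diet in aged mice and did not pass (SE 0.94, adjusted p = 0.136 by limma). Lcn2, another such protein, was at -2.44 (adjusted p = 0.233 by limma). These genes, as Myh3, were chosen after their values were seen.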
